A study of Homo sapiens with 6 samples.

How the data were processed

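The data are 6 RNA-seq libraries of human bone marrow mesenchymal stem cells, 3 from soft and 3 from stiff hydrogels. Per the labels' protocols, cells below passage 5 were grown in medium with 16.5% serum, mixed into gel precursor at about 10000 cells per microlitre and crosslinked by ultraviolet light at 30 mW/cm2 for 60 seconds. After 7 days they were homogenized in lysis buffer, total RNA was extracted and libraries were made for DNBseq sequencing. Groups and replicate numbers were taken from the sample titles. The deposited file is 1 table of RPKM values (reads scaled by gene length and library total) with an Entrez identifier and a symbol for each of 11724 genes. Per the submitters' processing notes, the authors' steps used bcl2fastq, STAR and the hg38 genome, with no versions given. The read counter, its treatment of strand and of reads shared between gene copies, and the filter that set which genes were listed are not given in the sources used here.

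The RPKM values were used as deposited by the authors, without further scaling. They were also examined for whole reads: for 100% of genes, the 6 values were whole multiples of what 1 read was worth, within 0.0001 reads, and 6 of 6 library totals came out as whole numbers. These totals were 19574946, 19234226 and 18904560 reads for soft replicates 1, 2 and 3 and 20006038, 19493006 and 19681357 for the stiff ones, and 99.1% to 99.2% of each total fell in the listed genes. The deposited values therefore carried no scaling between libraries beyond the division by the total. The implied gene lengths were multiples of 3 in 82.9% of genes, where 33.3% would be by chance, and had a median ratio of 0.993 to the coding length in GENCODE 29, so they are called coding lengths. They lay within 10% of that length in 78.14% of genes, so for the rest the name may not hold. Only 4 values in 3 genes were 0. Within a group, replicates differed by a mean chi-square per gene of 4.02 to 13.3 on the recovered reads, above the 1 that sampling noise alone gives, so no library was counted as a copy of another.

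Genes with an RPKM of at least 1 in at least 3 libraries were tested (11662, with 62 left out). Stiff and soft libraries were compared with limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), using lmFit and eBayes with a variance trend, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Fold changes are on the log2(RPKM + 1) scale, which understates changes of low genes. No replicate block was used, since the labels give no meaning to the shared replicate numbers. Before the data were examined, 37 gene lists were fixed, of lineage, mechanotransduction, matrix, iron, stress, cell cycle, immune and metabolic genes, markers of other cell types and signs of RNA quality, and the 31 with at least 5 tested members were tested with camera at a preset correlation of 0.01, two-sided, and adjusted over lists. Camera with an estimated correlation and fry were alternatives. The test design, the rule for named genes and most of the alternatives were fixed at the same time.

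Genes were named by that rule. It takes the 8 largest rises and the 8 largest falls among genes past the threshold whose groups do not overlap and whose mean RPKM is at least 5 in the higher group. It adds the 2 members with the smallest p of each leading list and of each other list that camera called, and always RUNX2, SOX9, PPARG, YAP1, WWTR1, CCN1, CCN2, LMNA and FTH1. Further list members named in the text, such as THBS1 or COL1A1, were chosen after their values were seen. Genes on the Y chromosome and XIST are not reported one by one, and some genes that the rule takes are not reported here.

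Positions, transcript lengths and GC content came from GENCODE 29 on GRCh38, the assembly also called hg38, through the Entrez identifier or else the symbol, and 11712 of the listed genes matched. Transcript length is that of the longest coding transcript, and the length of the principal transcript was an alternative. Trends with length or GC were removed from each library by loess with a span of 0.3. To compare a list with genes of like length, 10000 random lists were drawn, each member replaced by 1 of the 100 genes nearest in length. Members were drawn 1 by 1, so the random lists do not carry the correlation between genes of a list. Expression level was not matched. Other alternatives were pseudocounts of 0.1 and 5, no filter, a filter at an RPKM of 5, quantile normalization, median centring, rescaling to TPM, a robust variance, no variance trend, array weights, a replicate block, each library left out in turn, and limma voom on the recovered reads. Python 3.11.15 was used for the read recovery and the figures.

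The fit was tested on simulated data for stiff against soft, with reads for 11662 genes drawn at the observed depths. Of 50 genes changed at each size, 52% were recovered at 1.25-fold, 88% at 1.5-fold, 98% at 2-fold and 100% at 3-fold, with 7 false calls, and 0 genes were called when none was changed. In these runs genes varied independently with 1 shared dispersion and without a length trend, unlike in the libraries. The counts therefore do not cover false calls from differences of that kind. The read recovery was tested on 3001 simulated genes: 100% of genes came out whole up to a common factor and 98.3% exactly. The median gene had 465 reads in a library, but some named genes had few, such as CRIP1 with 22 to 61, and the number of libraries sets the precision: 3 against 3 cannot give an exact permutation p under 0.1.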

Results

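RNA was sequenced from human bone marrow mesenchymal stem cells, stromal cells that can form bone, cartilage and fat, after 7 days of culture inside light-cured hydrogels. Soft gels were cast from 5% (w/v) GelMA with 0.5% (w/v) photoinitiator, and stiff gels from the same mixture with MNP added to an iron content of 5 µg/mL, so that the gels differed in MNP as well as in stiffness. Each of the 2 groups had 3 libraries. The comparison of stiff with soft gels asks how the stiffness of the surrounding matrix changes the transcripts of these cells and their choice of fate. Expression was deposited as RPKM for 11724 genes, and the totals behind these values were 18904560 to 19574946 reads in the soft libraries and 19493006 to 20006038 in the stiff ones. The median gene had 465 reads in a library. The labels do not say whether the replicates were separate cultures or donors, so p-values measure only the spread among these libraries, which may be technical.

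Cells in stiff gels had higher transcript levels of the complement protein C3, of CEMIP, which takes part in breaking down hyaluronan, and of the Notch receptor NOTCH2. CEMIP (chromosome 15, 80779343 to 80951776 on GRCh38) stood at 48.5 ± 7.81 RPKM in soft and 85.6 ± 5.63 in stiff gels (SD, n = 3 each), a log2 fold change of 0.82 (SE 0.10, adjusted p = 0.020). C3 (chromosome 19, 6677704 to 6730562) went from 7.61 ± 1.65 to 14.3 ± 2.67 RPKM, and NOTCH2 (chromosome 1, 119911553 to 120069626) from 27.2 ± 1.52 to 41.6 ± 3.60. The other large rises were in HEG1, a transmembrane receptor of blood vessel cells, BMF, a pro-apoptotic BCL2 relative, the bradykinin receptor BDKRB2, the lipopolysaccharide-binding protein LBP, and KIAA0754, with log2 fold changes of 0.74, 0.64, 0.63, 0.61 and 0.67. KIAA0754 lies within the MACF1 locus, and the reads of the overlapping genes may not be separable. With the trend on transcript length described below removed, CEMIP and NOTCH2 still passed, at 0.68 and 0.42. C3, HEG1, BMF, BDKRB2 and LBP then stood at 0.75, 0.58, 0.57, 0.50 and 0.72 and did not pass (limma adjusted p = 0.060 to 0.086).

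The largest falls were in small genes, with coding lengths of 156 to 450 nucleotides. CRIP1, a LIM-domain protein (chromosome 14, 105486317 to 105488947), fell from 12.4 ± 0.882 to 6.27 ± 1.46 RPKM (SD, n = 3 each), a log2 fold change of −0.90 (SE 0.13, adjusted p = 0.020). The calcium-binding proteins S100A2 and S100A4 had log2 fold changes of −0.72 and −0.58, and the PCNA-binding factor PCLAF, the protease inhibitor CST6, PLAC9 and ST20 of −0.52, −0.51, −0.57 and −0.54. RPL39L, a ribosomal protein gene whose reads may be shared with its close relative RPL39, stood at −0.58. With the trend on transcript length described below removed, none of these falls passed. CRIP1, S100A2 and PCLAF then stood at −0.72, −0.50 and −0.43 (limma adjusted p = 0.063, 0.063 and 0.072). S100A4, RPL39L, PLAC9, ST20 and CST6 stood at −0.29, −0.32, −0.31, −0.32 and −0.25. CRIP1, S100A2, S100A4 and ST20 had only 21 to 62 reads in a library, and the voom fit did not call S100A4 and ST20 (adjusted p = 0.053 and 0.067).

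In all, 1304 of 11662 tested genes changed (limma on log2(RPKM + 1), Benjamini-Hochberg adjusted p under 0.05), 546 of them higher and 758 lower in stiff gels. Changes were small: limma called 0 genes with a change of at least 2-fold, against 3583 genes of any size at an unadjusted p under 0.05, and a voom fit of the reads recovered from the RPKM values called 8. The 3 stiff libraries lay wholly above or below the 3 soft ones in 35.9% of genes, where chance gives 10% for a single gene. Genes vary together and the share in other splits was not examined, so this excess is no test against chance. The first principal component held 47.6% of the variance and separated the groups, with soft replicate 3 at −15.6, the other soft libraries at −6.36 and −5.54, and the stiff libraries between 6.10 and 10.7. The count of calls rested on single libraries: it was 146 without soft replicate 3 and 0 without stiff replicate 1 or stiff replicate 3, where 2506 and 2674 genes had an unadjusted p under 0.05, so no single gene was called under every such omission. Rescaling each library to TPM moved the median log2 fold change of all genes by 0.10 and turned the split from 41.9% of calls higher to 88.5% of 1950, and quantile normalization gave 61.6% of 631.

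**Figure D1:**
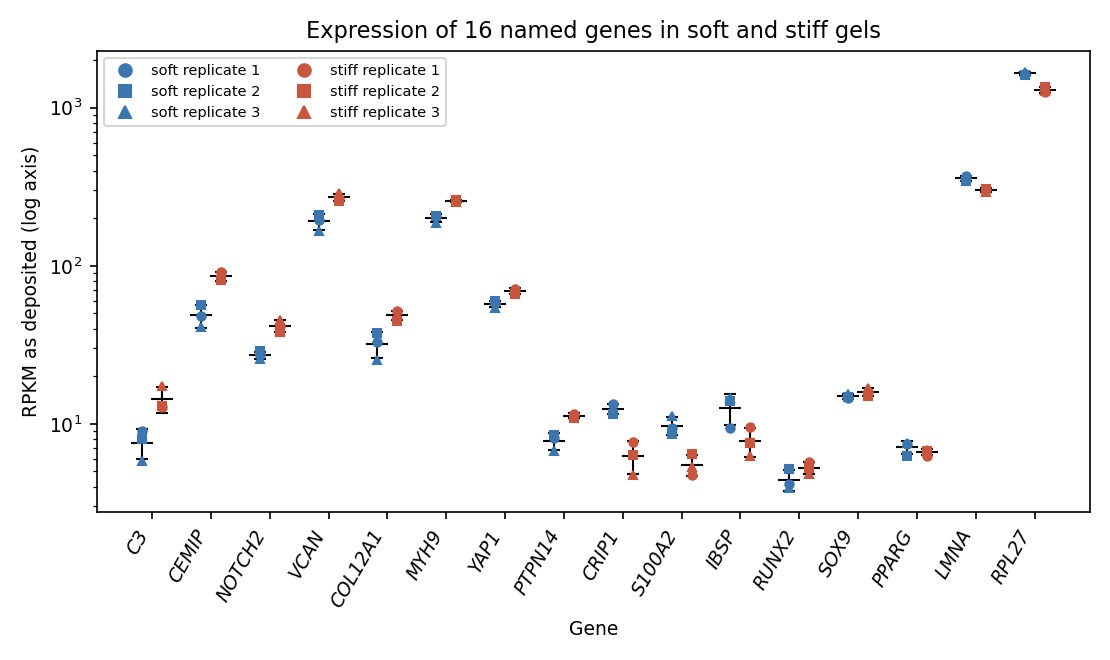
RPKM (log axis) of 16 named genes in each of the 3 soft and 3 stiff libraries, with the bar at the group mean and whiskers of 1 SD. The 3 stiff libraries lie above all soft ones for CEMIP, NOTCH2, VCAN and YAP1 and below them for CRIP1, LMNA and RPL27, while RUNX2, SOX9 and PPARG overlap.

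Of 33 tested matrix glycoprotein and proteoglycan genes, 13 rose and 0 fell (16 and 2 adjusted over the list alone), with a median log2 fold change of 0.17. The proteoglycans VCAN and HSPG2 rose from 190.7 ± 23.2 to 270.7 ± 15.3 RPKM and from 28.999 ± 2.81 to 39.8 ± 2.53 (SD, n = 3 each), and THBS1, FBN1, FN1 and the basement membrane protein NID1 by log2 fold changes of 0.53, 0.45, 0.39 and 0.48. Of 21 collagen genes, 5 rose and 0 fell (10 and 0 adjusted over the list alone), with a median of 0.20. COL12A1 and COL14A1, which associate with collagen fibrils, rose by 0.60 (SE 0.12) and 0.42 (SE 0.10), whereas COL1A1 and COL1A2, the chains of type I collagen, had log2 fold changes of 0.11 and 0.16 that did not pass (adjusted p = 0.29 and 0.12). Without soft replicate 3, 3 and 1 genes of these lists rose, with medians of 0.17 and 0.15 and both lists still called by camera. Camera placed both lists above other genes (adjusted p = 1.2e-05 and 9.6e-05), and neither call held with an estimated correlation (adjusted p = 0.61 and 0.72). With the transcript length trend removed, the medians were 0.11 and 0.08 and 0 genes of either list passed. VCAN and COL12A1 then stood at 0.32 and 0.42 (adjusted p = 0.068 and 0.080). The collagen call was lost with the coding length trend removed (adjusted p = 0.22). Among 52 matrix remodelling enzymes, the protease ADAMTS12 rose (log2 fold change 0.37) and the collagen-degrading cathepsin CTSK fell (−0.26), and the list was not called (camera adjusted p = 0.33). With the transcript length trend removed, ADAMTS12 and CTSK stood at 0.22 and −0.12 and did not pass (limma adjusted p = 0.13 and 0.33).

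Of 35 focal adhesion and integrin genes, 9 rose and 0 fell (10 and 0 adjusted over the list alone), with a median log2 fold change of 0.10. The collagen-binding integrin ITGA2 rose from 41.2 ± 2.84 to 57.0 ± 6.52 RPKM (SD, n = 3 each), and the actin-linked adaptors VCL and TLN1 by log2 fold changes of 0.28 and 0.28. Without soft replicate 3, 0 of these genes passed, although the median stayed at 0.10 and camera still called the list (adjusted p = 0.00084). Camera called it with all libraries (adjusted p = 0.00021), but not with an estimated correlation (adjusted p = 0.61), and with the coding length trend removed it was lost (adjusted p = 0.11) and 0 of its genes passed. Its median lay at percentile 86.9 of random lists matched on coding length and 86.8 of those matched on transcript length, so it did not stand out from genes as long. Of 31 actin and contractile genes, 3 rose and 3 fell (4 and 5 adjusted over the list alone), and the list was not called (adjusted p = 0.60). The nonmuscle myosin heavy chain MYH9 rose from 200.2 ± 10.995 to 256.9 ± 2.98 RPKM, and MKL2, a coactivator of serum response factor, from 2.09 ± 0.140 to 3.52 ± 0.183. With the transcript length trend removed, MYH9 and MKL2 stood at 0.22 and 0.39 on the log2 scale and did not pass (limma adjusted p = 0.068 and 0.070). The smaller contractile genes MYL6, TPM2 and RHOC fell by 0.26, 0.22 and 0.25 on the log2 scale.

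YAP1, the transcriptional coactivator that responds to cell tension, rose from 57.4 ± 2.88 to 69.2 ± 2.86 RPKM (log2 fold change 0.27, SE 0.06, adjusted p = 0.027), and its relative WWTR1 stood at 112.5 ± 3.77 and 127.5 ± 8.51 (SD, n = 3 each; adjusted p = 0.075). Of 21 YAP/TAZ target genes, PTPN14 and LATS2 rose, GADD45A fell, and the median was 0.16 (4 higher and 1 lower adjusted over the list alone). PTPN14 and LATS2 are known to restrain YAP, and GADD45A acts in growth arrest. With the transcript length trend removed, YAP1, PTPN14 and GADD45A stood at 0.17, 0.30 and −0.09 and did not pass (limma adjusted p = 0.13, 0.079 and 0.61). YAP1 was also not called without soft replicate 3 (limma adjusted p = 0.063). The classical targets CYR61 and CTGF, named CCN1 and CCN2 in current use, had log2 fold changes of 0.08 (SE 0.09) and 0.19 (SE 0.11) and did not pass (adjusted p = 0.55 and 0.28). Camera called the list (adjusted p = 0.0065), but not with an estimated correlation (adjusted p = 0.85) nor without soft replicate 3 (adjusted p = 0.10). Of 30 genes of the TGF-beta and BMP response, 5 rose and 2 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.15). The latent TGF-beta binding proteins LTBP2 and LTBP1 rose by 0.35 and 0.27, and the BMP-induced genes ID1 and ID3 fell by 0.27 and 0.24. With the transcript length trend removed, LTBP2 and LTBP1 stood at 0.20 and 0.15 and did not pass (limma adjusted p = 0.13 and 0.16). Neither was called without soft replicate 3 (limma adjusted p = 0.052 and 0.061). In the Wnt list, 2 of 24 genes rose and 0 fell (4 and 0 adjusted over the list alone; camera adjusted p = 0.14): the agonist RSPO3, at 0.995 ± 0.075 and 1.59 ± 0.115 RPKM, and the antagonist SFRP1. RSPO3 had 15 to 27 reads in a library, and the voom fit called neither (adjusted p = 0.078 and 0.090).

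The lineage lists gave few calls. Of 11 osteogenic genes, 1 passed (also 1 adjusted over the list alone): IBSP, the bone matrix protein bone sialoprotein, fell from 12.6 ± 2.80 to 7.78 ± 1.61 RPKM (SD, n = 3 each; log2 fold change −0.62, SE 0.16, adjusted p = 0.038), although its soft and stiff libraries overlapped. IBSP was still called without soft replicate 1, but not with any other library left out (limma adjusted p = 0.077 to 0.13). It was also not called with no variance trend or with the coding or transcript length trend removed (limma adjusted p = 0.066, 0.092 and 0.19). The osteoblast regulator RUNX2 had a log2 fold change of 0.21 (SE 0.10) with an adjusted p of 0.20. None of 6 chondrogenic genes passed, and the cartilage regulator SOX9 stood at 14.9 ± 0.479 and 15.9 ± 0.943 RPKM and COMP at 15.8 ± 3.12 and 12.3 ± 1.23. Of 6 adipogenic genes, 0 passed over all genes and 1 was lower adjusted over the list alone. PPARG, the regulator of fat cell formation, had a log2 fold change of −0.09 (SE 0.08), the lipolysis inhibitor G0S2 of −0.37 and the fatty acid desaturase SCD of 0.36. Camera called none of the 3 lists (adjusted p = 0.94, 0.87 and 0.94), and relative to all genes the osteogenic median was −0.07, with −0.06 after rescaling to TPM and 0.06 under quantile normalization. The direction that camera gave the osteogenic list, higher, was opposite to that of its median and mean.

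Of 50 chromatin modifier genes, 9 rose and 1 fell (13 and 1 adjusted over the list alone), with a median of 0.10. The acetyltransferase genes CREBBP, EP300 and KAT6A rose by 0.38, 0.29 and 0.31, and the methyltransferase genes KMT2A, KMT2D and SETD2 by 0.45, 0.31 and 0.28. LMNA, which encodes the nuclear lamins A and C, fell from 357.7 ± 12.3 to 300.9 ± 8.81 RPKM (SD, n = 3 each; log2 fold change −0.25, SE 0.05, adjusted p = 0.024). Without soft replicate 3, 0 genes of the list passed, although the median was 0.08 and camera still called the list (adjusted p = 0.00053). Camera called it as higher with all libraries (adjusted p = 0.00021), but not with an estimated correlation (adjusted p = 0.61) or with the coding length trend removed (adjusted p = 0.50), and its median lay at percentiles 73.1 and 88.1 of random lists matched on coding and on transcript length.

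Iron genes were examined because the stiff gels carried iron. Of 18 tested, IREB2, an iron-responsive RNA-binding protein, rose from 11.02 ± 0.812 to 14.3 ± 0.621 RPKM (SD, n = 3 each; adjusted p = 0.024), and 0 fell (1 and 0 adjusted over the list alone; camera adjusted p = 0.17). The log2 fold change of IREB2 went from 0.35 to 0.23 with the transcript length trend removed (limma adjusted p = 0.14). It was also not called without soft replicate 3 (limma adjusted p = 0.061). The ferritin heavy chain FTH1 stood at 26450 ± 3502 and 23363 ± 1524 RPKM (log2 fold change −0.17, SE 0.11, adjusted p = 0.29), and the iron and zinc transporter SLC39A14 had an adjusted p of 0.063. In the list of NRF2 and oxidative stress genes, 1 of 24 rose and 3 fell (1 and 4 adjusted over the list alone; camera adjusted p = 0.17). The mitochondrial superoxide dismutase SOD2 rose by 0.26, and the cytosolic enzyme SOD1 fell by 0.24, as did GPX4 and PRDX1 by 0.29 and 0.22. The longest annotated coding transcripts of SOD2 and SOD1 have 14266 and 966 nucleotides, and whether these are the ones expressed was not examined. With the transcript length trend removed, SOD2 and SOD1 stood at 0.07 and −0.02 (adjusted p = 0.66 and 0.89).

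Of 76 cytosolic ribosomal protein genes, 64 fell and 0 rose (76 and 0 adjusted over the list alone), with a median log2 fold change of −0.29. RPL27 fell from 1651 ± 35.1 to 1293 ± 49.9 RPKM and RPS20 from 1609 ± 58.6 to 1244 ± 74.6 (SD, n = 3 each). These genes have many processed pseudogenes, and how shared reads were counted is not given in the sources used here. Of 41 oxidative phosphorylation genes, 21 fell and 0 rose (34 and 0 adjusted over the list alone), with a median of −0.20, among them COX5B (−0.31) and NDUFB8 (−0.28). Of 42 cell cycle genes, UBE2C and CCNB1, which act in mitosis, fell by 0.34 and 0.25 and 0 rose (0 and 0 adjusted over the list alone), with a median of −0.11. Without soft replicate 3, 4, 1 and 1 genes of these lists fell, with medians of −0.27, −0.18 and −0.13 and all 3 lists still called by camera. Camera called all 3 lists as lower (adjusted p = 1.2e-26, 3.3e-11 and 0.040), and none was called with an estimated correlation (adjusted p = 0.61, 0.61 and 0.85). With the transcript length trend removed, the oxidative phosphorylation median went to −0.02 and its call was lost (adjusted p = 0.053). The ribosomal protein median went to −0.09 and the cell cycle median to −0.10, and 0 genes of these lists passed. COX5B, NDUFB8 and RPL27 then stood at −0.04, −0.01 and −0.09 (adjusted p = 0.73, 0.91 and 0.36) and RPS20 at −0.24 (adjusted p = 0.068). UBE2C and CCNB1 then stood at −0.10 and −0.15 (limma adjusted p = 0.64 and 0.33). The cell cycle call was also lost without soft replicate 1, soft replicate 2 or stiff replicate 3 (adjusted p = 0.098, 0.19 and 0.22) and with a pseudocount of 5 (adjusted p = 0.089).

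**Figure D2:**
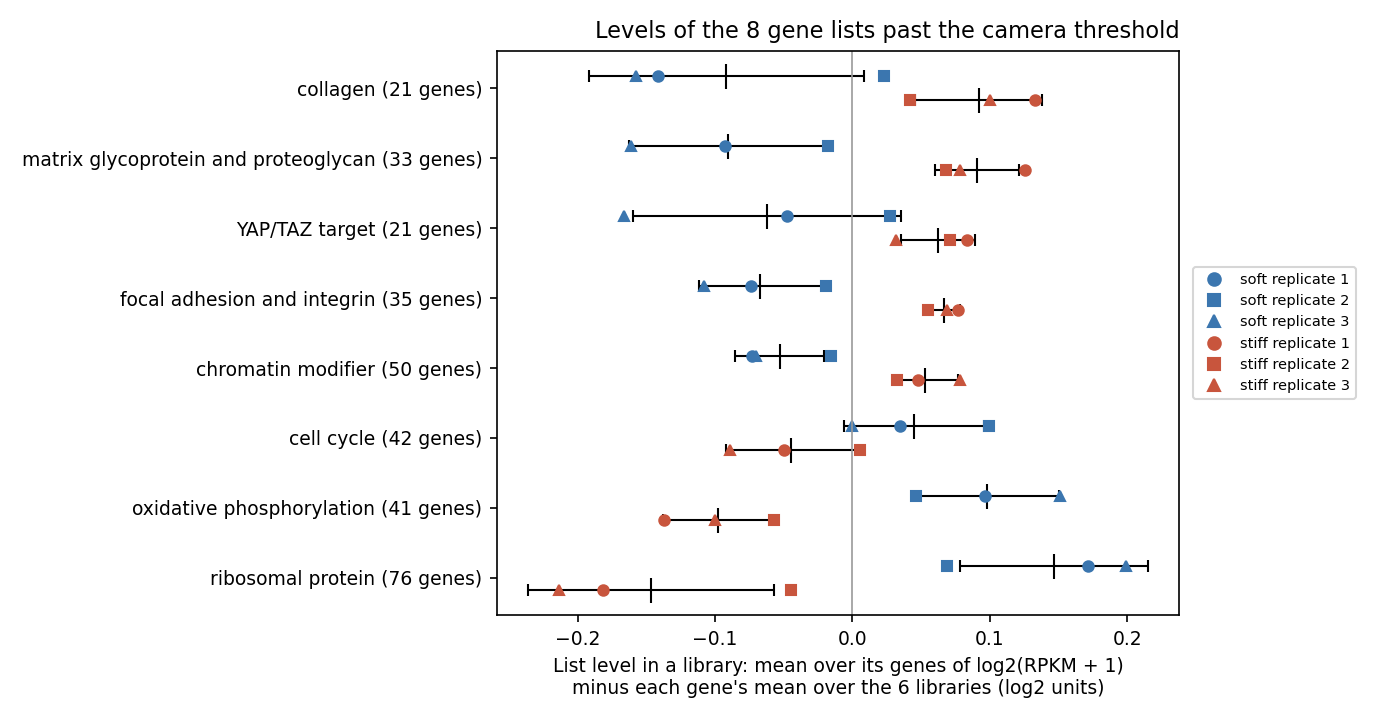
Level of the 8 gene lists called by camera in each library, as the mean over a list's genes of log2(RPKM + 1) after each gene's mean over the 6 libraries was subtracted, with the bar at the group mean and whiskers of 1 SD over 3 libraries. The soft and stiff libraries overlap only for the cell cycle list, and the ribosomal protein list runs from 0.20 in soft replicate 3 to −0.21 in stiff replicate 3.

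Other lists were not called by camera. In stress and signalling lists, ICAM1 and CXCL12 rose among 28 NF-kB and cytokine genes (1 higher adjusted over the list alone; camera adjusted p = 0.12), MDM2 and ZMAT3 rose and GADD45A fell among 22 p53 and senescence genes, and SEL1L and DNAJC3 rose while ATF4 and DDIT3 were among 5 that fell of 27 unfolded protein response genes. The counts of higher and lower genes were 1 and 2 of 34 for interferon response, 1 and 0 of 31 for hypoxia and glycolysis, 2 and 1 of 23 for immediate early genes, 0 and 1 of 16 for heat shock, 1 and 2 of 30 for lysosome and autophagy, 0 and 0 of 24 for cholesterol synthesis, 0 and 1 of 7 for metallothioneins, and 0 and 0 of 7 for replication-dependent histones. Camera pointed upward for the interferon list, whose median and mean were below 0, and for the immediate early list, whose median was −0.02 and mean 0.02. Of 19 stromal cell surface genes, the platelet-derived growth factor receptors PDGFRA and PDGFRB rose by 0.44 and 0.29, and CD63, CD151 and S100A4 fell. Markers of other cell types were few: 6 haematopoietic genes (0 passed), 4 endothelial (0 passed), 4 neural (TUBB3 lower), 3 epithelial (KRT19 lower) and 5 tendon genes (TNC higher, SCX lower), while skeletal muscle, haemoglobin and mitochondrial mRNA genes were not among the genes listed.

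The change in stiff gels followed the length of a gene's transcript. Across 11626 genes, which are not independent replicates, the log2 fold change had a Spearman correlation of 0.66 with annotated transcript length. When genes were divided into 5 equal bins by transcript length, the shortest bin, which held 56 of the 76 ribosomal protein and 26 of the 41 oxidative phosphorylation genes, had a median of −0.17, with 4 genes higher and 549 lower. The longest bin had a median of 0.14, with 382 higher and 16 lower. Each stiff library showed the trend against each soft one, at 0.038 to 0.074 log2 units per doubling of transcript length in stiff and −0.030 to −0.10 in soft libraries. With a trend on transcript length taken out of each library, 16 genes passed the test (5 higher, 11 lower), CEMIP and NOTCH2 among them. Camera then called the matrix glycoprotein (adjusted p = 4.2e-05), collagen (0.045), YAP/TAZ target (0.045), cell cycle (0.035) and ribosomal protein (2.1e-11) lists and also the NF-kB and cytokine list (0.0025), but not the focal adhesion (0.053), oxidative phosphorylation (0.053) or chromatin modifier list (0.19). None of these calls was made with an estimated correlation (adjusted p = 0.74 for each list), and 0 genes of these lists passed. The oxidative phosphorylation median went from −0.20 to −0.02. The medians went from −0.29 to −0.09 for the ribosomal protein, 0.20 to 0.08 for the collagen and 0.10 to 0.04 for the chromatin modifier list, and from 0.10 to 0.05 for the focal adhesion, 0.16 to 0.08 for the YAP/TAZ target, 0.17 to 0.11 for the matrix glycoprotein and −0.11 to −0.10 for the cell cycle list. Of the 9 other splits of the libraries, 2, 2, 3, 3 and 7 also called the matrix glycoprotein, collagen, YAP/TAZ target, cell cycle and ribosomal protein lists with this trend removed, and 6 the NF-kB list. The NF-kB level rested on stiff replicate 3, at 0.39 against −0.04 and −0.002 in the other stiff and −0.23 to 0.03 in the soft libraries. With this trend removed, levels of soft and stiff libraries also overlapped for the collagen, YAP/TAZ target and cell cycle lists. For collagen, soft replicate 2 stood at 0.04 and stiff replicate 2 at 0.007. For YAP/TAZ targets, soft replicate 2 stood at 0.03 and stiff replicate 3 at 0.006. For the cell cycle, stiff replicate 2 stood at 0.01 and soft replicate 3 at −0.03. The matrix glycoprotein and ribosomal protein levels did not overlap.

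**Figure D3:**
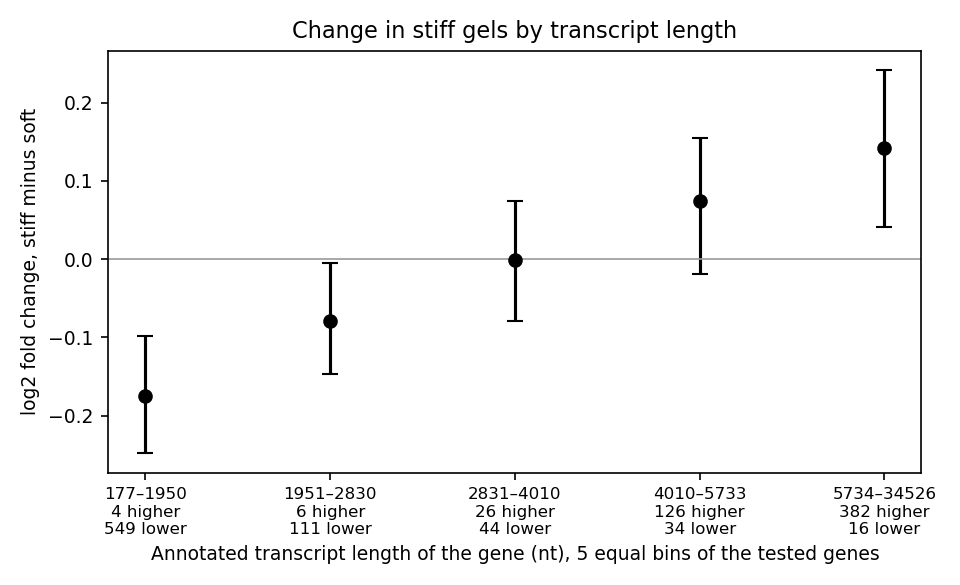
Median log2 fold change (stiff minus soft) of the tested genes in 5 equal bins of annotated transcript length in nucleotides, with whiskers from the 25th to the 75th percentile over genes and the counts of genes past the test under each bin. Medians go from −0.17 in the shortest to 0.14 in the longest bin.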

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

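The voom fit and the removal of length and GC trends were chosen after seeing the data. None of the 45 named genes called and none of the 8 lists called changed direction. Of all 1304 genes called, 61 changed sign with the transcript length trend removed, 54 with the principal transcript length trend, 5 with the coding length trend, 3 with that trend removed without soft replicate 3 and 1 under quantile normalization, none of them past the threshold there. Values near 0 that passed in no setting changed sign, and the cause was not tested: PPARG (0.015 after rescaling to TPM, 0.025 and 0.026 with the transcript and principal transcript length trend removed), FTH1 (0.022 and 0.0073 with these, 0.045 with the coding length trend removed without soft replicate 3) and CYR61 (−3.52e-05 in this last setting, −0.035 to 0.15 leaving out 1 library at a time). Camera or fry turned the direction of uncalled lists, at adjusted p for osteogenic genes of 0.74 (TPM), 1.00 (array weights), 0.91, 0.94 and 0.78 (coding, transcript and principal transcript length), 0.97 (transcript length with an estimated correlation), 0.78 (coding length without soft replicate 3), 0.90 (fry) and 0.78 to 0.99 leaving out 1 library, for chondrogenic genes of 0.94 (no filter) and 0.56 to 0.99, for adipogenic genes of 0.99 (RPKM of 5), 0.71 (coding length), 0.95 (fry) and 0.64 to 0.95, for actin and contractile genes of 0.82 (coding length without soft replicate 3) and 0.27 to 0.97, and for NRF2 genes of 0.82 (the same). Leaving out 1 library at a time gave 0 to 1299 changed genes, 0 to 441 higher, 0 to 858 lower and 0 to 1 changed at least 2-fold, with 0 calls without stiff replicate 1 or stiff replicate 3 (2506 and 2674 genes at an unadjusted p under 0.05), 146 without soft replicate 3, 475 lower without soft replicate 2 and 337 higher without stiff replicate 2. Fewer libraries may be part of the cause, which was not tested. Quantile normalization called 631 genes (242 lower), rescaling to TPM 1726 higher and 224 lower, and no variance trend 504 (291 higher, 213 lower); the TPM split follows from the shift of all genes by 0.10, and for the others the cause was not tested. The voom fit called 1912 genes, 958 of them higher, and 8 changed at least 2-fold. Genes changed at least 2-fold numbered 5 with a pseudocount of 0.1, which compresses low genes less, and 1 each with a filter at an RPKM of 5, after rescaling to TPM and with the replicate block. Removing the coding length trend left 133 genes (91 higher, 42 lower), removing the transcript length trend 16 (5 higher, 11 lower), the principal transcript length trend 17 (9 higher, 8 lower), and the coding length trend without soft replicate 3 left 0 (2227 at an unadjusted p under 0.05) and 5 lists. Camera called 0 lists with an estimated correlation, also with the transcript length trend removed, and fry 0, with a smallest adjusted p of 0.61, 0.74 and 0.077. Other alternatives kept each count within 1.5 times, between 1291 and 1827 changed genes. Of 45 named genes called, 2 of the 44 with a transcript length stayed past the threshold after its trend was removed, and 22 of 45 without soft replicate 3. With the replicate block 1444 genes changed (588 higher, 856 lower). Deviations of same-numbered libraries had correlations of −0.01, −0.06 and 0.14, the last the highest of all pairs, and soft replicate 1 correlated best with stiff replicate 2 (0.13). All were near 0, and with 3 libraries in a group they cannot settle whether the numbers pair the libraries. Depth limits genes with few reads: the median gene had 465 in a library, but CRIP1 22 to 61, S100A4 21 to 42, ST20 28 to 56 and RSPO3 15 to 27, and voom lost the last 3.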

Other observations

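The families and genes in this paragraph and the next and the tests on whole transcript length were chosen only after the result was seen. Of 78 mitochondrial ribosomal protein genes, 22 fell and 0 rose, with a median log2 fold change of −0.18 (−0.07 after rescaling to TPM, which moved all genes by 0.10), and MRPL55 and MRPL57 fell by 0.42 and 0.35. Of 38 proteasome subunit genes, 10 fell and 0 rose (median −0.16, and −0.04 after rescaling to TPM), PSMB3 and PSMA7 among them. Of 9 genes of the calcium-binding S100A family, 6 fell and 0 rose: S100A6 stood at 1984 ± 131.4 RPKM in soft and 1509 ± 108.7 in stiff gels (SD, n = 3 each), and S100A13 at 524.1 ± 36.5 and 374.2 ± 17.9. Under quantile normalization the medians of these families were −0.13, −0.07 and −0.21. Against random lists matched on transcript length, the medians of these families lay at percentiles 4.79, 14.7 and 0.46, and against lists matched on coding length at 0.01, 0 and 0.43, so whether the first 2 families stood out depended on the length used. Of the 8 other families examined, the translation initiation factors were low against both (1 higher and 5 lower of 50, percentiles 0.01 and 0.19). Their median was −0.12, but −0.005 after rescaling to TPM and −0.03 under quantile normalization. The other 7 lay between percentiles 2.61 and 95.8 by both lengths, such as plexins and semaphorins (53.7 and 63.9) and 425 zinc finger genes (42.0 and 75.3, with 6 higher and 7 lower).

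Several signalling genes outside the named set were higher in stiff gels. TEAD1, a DNA-binding partner of YAP, rose from 18.8 ± 1.78 to 27.4 ± 1.45 RPKM, NOTCH3 from 37.4 ± 1.53 to 44.9 ± 3.74 and the semaphorin receptor PLXNA4 from 2.92 ± 0.116 to 4.79 ± 0.825 (SD, n = 3 each; limma adjusted p = 0.020, 0.043 and 0.021). Of 4 TEAD genes tested, TEAD1 was the 1 called, and the family median was 0.02. The neutrophil attractant CXCL1 stood at 6.31 ± 0.880 and 13.9 ± 7.53 RPKM and did not pass (adjusted p = 0.050). PTHLH, the parathyroid hormone-related protein, went the other way, at 41.4 ± 25.7 RPKM in soft and 17.7 ± 2.62 in stiff gels, the largest absolute log2 fold change of the tested genes (−1.03), and did not pass either (adjusted p = 0.053). With the transcript length trend removed, the rises called besides CEMIP and NOTCH2 were in LGALS2, MSMP and GVQW2, and the 11 falls included SNRPD1, PSMG4, TRAPPC5 and TMED3. These rises have short annotated transcripts (591, 670 and 327 nucleotides), and GVQW2 stood at only 0.480 RPKM in soft gels. The named falls have long ones (4909, 4603, 5498 and 16555). SUGT1, ABI2 and KCNC4, also among the falls, did not pass without this removal (limma adjusted p = 0.11, 0.081 and 0.051). Whether the longest annotated transcript is the one expressed was not examined, so the removal may overcorrect such genes.

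The count of 1304 changed genes was reached in 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, and the counts of 546 higher and 758 lower genes likewise in 1 each, with a highest count of 0 in the other splits. A count of 0 genes changed at least 2-fold came out in 10 of 10 splits, with 0 as the highest of the others. With 10 splits the share cannot be under 0.1, so these counts do not settle whether chance can be excluded. The 8 lists called by camera were matched or exceeded in 8 of the 10 splits, the real one included, with up to 14 lists in another split. As deposited, 6 of the 9 other splits also called the ribosomal protein list. The oxidative phosphorylation, matrix glycoprotein, focal adhesion and YAP/TAZ target lists were called in 5 each. The collagen, chromatin modifier and cell cycle lists were called in 3 each. The preset correlation of 0.01 lay below the correlation estimated within most called lists, 0.80 for ribosomal protein and 0.48 for oxidative phosphorylation genes.

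Long genes were higher and short genes lower in stiff gels, with a Spearman correlation across genes of 0.66 for transcript length and 0.49 for coding length. The tables argue against GC content as the source of the slope on coding length, since 99.96% of it was left after the GC trend was removed. The trend on transcript length was not examined after that removal, so GC content stays open there. Across genes the log2 fold change had a Spearman correlation of −0.24 with GC content. Within each of 5 bins of coding length the correlation with transcript length was at least 0.505, so the untranslated parts of a transcript may matter as well, as a difference in RNA integrity or fragment selection between libraries could produce. The slopes did not overlap between groups (the lowest stiff slope exceeded the highest soft slope by 0.0391), which had been set beforehand as the sign against differences between single libraries, but 3 libraries separate from 3 by chance in 10% of genes or measures, so the bound was too weak and the explanations cannot be told apart here. Whether stiffness, MNP or RNA handling produced the trend stays open, as no label records RNA integrity or a library batch.

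Ribosomal protein and oxidative phosphorylation genes were lower in stiff gels, and both sets have short transcripts. The length trend could account for part or most of the ribosomal protein change, depending on the length used. Removing it took the median from −0.293 to −0.095 on transcript length and to −0.156 on coding length. On coding length 2 genes still fell, RPS9 and RPS18, with implied lengths of 5850 and 2398 nucleotides against a list median of 475.5. They were thus corrected as long genes, and their log2 fold changes went from −0.31 and −0.31 to −0.46 and −0.36. Whether these lengths are right was not examined. For the whole list, however, 0 of 10000 random lists matched on coding length and 0 of 10000 matched on transcript length had a median as low. These lists were drawn gene by gene, without the correlation estimated within the list (0.80). Their spread may therefore be too narrow to exclude a length trend as the whole cause. Expression level was not matched either, and ribosomal protein genes are highly expressed. Across genes the log2 fold change had a Spearman correlation of −0.27 with the mean log2 value, so a trend with expression level stays open. The ribosomal protein median was −0.268 without soft replicate 3, which argues against that library alone. For oxidative phosphorylation genes, 341 of 10000 lists matched on transcript length and 18 of 10000 matched on coding length were as low, so a trend on whole transcripts could account for their change and a trend on coding length fits less well. Relative to all genes the ribosomal protein median was −0.278 as deposited, −0.278 after median centring and −0.267 after rescaling to TPM, which move genes nearly alike. Under quantile normalization it was −0.102 (SE 0.0091), close to the bound of 0.1 set beforehand. This SE is far below the differences between libraries. As deposited, the list level ran from 0.069 to 0.20 in soft and −0.21 to −0.045 in stiff libraries. Scaling therefore stays open, and quantile normalization also equalizes the highest ranks, which these genes hold. A lower output of ribosomal protein transcripts in stiff gels is therefore a hypothesis with this limit, and stiffness and MNP were not varied apart.

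Matrix glycoprotein, proteoglycan and collagen genes were higher in stiff gels, and their transcripts are long. Of 10000 random lists, 9991 matched on coding length and 10000 matched on transcript length had a median at or below theirs. These lists were drawn gene by gene, without the correlation estimated within the matrix glycoprotein and collagen lists (0.23 and 0.40). Their spread may therefore be too narrow to exclude a length trend as the whole cause. The median of both lists together was 0.154 without soft replicate 3, against 0.18 with it, so that library alone is not the source. Relative to all genes, the median was 0.19 as deposited, 0.19 after median centring and 0.20 after rescaling to TPM, which move genes nearly alike and so could hardly differ. It was 0.29 under quantile normalization. A greater output of matrix transcripts in response to the gel is a hypothesis that no test here examined: RNA integrity, batch and the added MNP could not be separated from stiffness, the lists' calls were lost with an estimated correlation, and the medians of 0.17 and 0.20 fell to 0.11 and 0.08 with the transcript length trend removed.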
